A study of Homo sapiens with 16 samples.

How the data were processed

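RNA was measured by sequencing in SK-OV-3 cells, an established human ovarian carcinoma line. The cells carried either a scrambled control shRNA (shScramble) or 1 of 3 shRNAs against PRMT1 (shPRMT1 #1, #3 and #5). PRMT1 is the main enzyme that places asymmetric dimethylarginine on proteins. Each of the 4 cell populations was left untreated or given cisplatin, a DNA-crosslinking drug, at 20 µM for 24 h. The labels give 2 biological replicates for each of the 8 groups, 16 libraries in all, and do not say how the replicate cultures were kept apart. RNA was extracted with RNeasy Plus Micro and libraries were made with the TruSeq RNA v2 kit, per the labels' protocols. That kit does not mark the strand, so reads of overlapping and antisense genes cannot be told apart.

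The authors deposited a single table of 57820 genes holding linear RPKM values (reads per kilobase of gene model, scaled to the library total), with 1 column per library, per the file headers. The submitters' processing notes name HISAT2 and DESeq2 without a version or a role, and the genome builds GRCh37 and mm9. Gene identifiers and coordinates in the table are human and are quoted as the file gives them, on GRCh37. The counting program, the annotation release, the treatment of duplicate reads and the scaling of the libraries are not given in the sources used here. Gene symbols are those of the file, so that CXCL8 appears as IL8, PRMT9 as PRMT10 and CCN2 as CTGF.

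RPKM values that come from whole reads lie on steps set by gene length and library total. The steps were used to recover reads for 40649 of the 40649 genes with any value above 0 (100%, each within 0.01 reads of a whole number). The recovered library totals ran from 12289319 to 16039782 reads, the largest 1.31 times the smallest. A floor of 3 reads in a gene model of 2 kb corresponded to 0.094 to 0.122 RPKM. Floors cover counting error only, because reads without molecular identifiers are not independent molecules. Chi-square per degree of freedom between the recovered reads of the 2 replicates ran from 5.79 to 39.96 over the 8 groups, so no library pair agreed within sampling noise.

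The design was fixed before the data were examined and assumed read counts, with a stated form for a table holding only RPKM. That form was used: limma 3.58.1 with a trended prior in R 4.3.3, on log2(RPKM + 1), over the 18149 genes with at least 1 RPKM in 2 or more libraries. All 16 libraries entered 1 model of 8 group means. Log2 differences are therefore on the log2(RPKM + 1) scale, which understates the change of genes with low values. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. The 5 averaged comparisons were cisplatin against untreated in shScramble cells, the same in shPRMT1 cells as the mean of the 3 shRNAs, shPRMT1 against shScramble untreated and under cisplatin, and the difference between the 2 cisplatin responses. Each shRNA was also compared alone.

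Named genes were chosen by a rule. For each averaged comparison it took the 8 largest increases and the 8 largest decreases among called, named genes with a mean of at least 5 RPKM on the higher side and libraries of both sides not overlapping. For the difference between responses, each of the 3 shRNAs had to lie on the same side. Up to 4 called members of each list with the lowest adjusted p were added, and PRMT1, IL6, IL8, IL1A and IL1B were taken everywhere. Some genes that met the rule are not reported. The 16 lists were SASP factors (secreted factors of senescent cells), NF-kB feedback and target genes, p53 target genes, S phase and DNA replication, G2 and mitosis, DNA damage response and repair, protein arginine methyltransferases other than PRMT1, interferon-stimulated genes, ATF4 and endoplasmic reticulum stress, AP-1 and immediate early genes, NRF2 and oxidative stress, metallothioneins, cholesterol synthesis, cytosolic ribosomal proteins, epithelial and mesenchymal genes, and markers of other cell types (fibroblast, endothelium, leukocyte). Of the list members, 1 marker of other cell types was not matched in the table. Some genes belong to more than 1 list, ATF3 among them. Lists were tested with camera in limma at a preset correlation of 0.01, adjusted over the 16 lists of a comparison, and again with an estimated correlation and with fry.

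The replicate numbers were checked for pairing before the calls of the different models were compared. The difference between replicate 1 and replicate 2 correlated across genes in all 28 pairs of groups, at 0.30 to 0.70. The principal component holding 14.6% of the variance placed replicate 1 on the same side of replicate 2 in 8 of 8 groups. The numbers were therefore read as pairs, and values from a model with the replicate number as a block are given where they change a call or move a count by more than 1.5 times.

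The procedure was tested on simulated data in which 200 of the 18149 genes were changed. For cisplatin against untreated in shScramble cells it called 35.8% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 90.9% of those changed 4-fold, with 8 unchanged genes called. For the difference between responses the shares were 25.4%, 56.7% and 84.8%, with 8 unchanged genes called. Unchanged groups against shared shScramble libraries were simulated 100 times.

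Alternatives were quantile normalization, no filter on low values, a pseudocount of 0.1, the replicate block, only the libraries of a comparison, each library left out in turn, and calls required of each shRNA. Added after the data had been seen were limma voom on the recovered reads with median-of-ratios scaling, inversion of a ceiling of 2 reads per base of gene model, and each shRNA left out of the mean. GC content was taken from reference transcripts matched by gene identifier, for 17484 of 18149 genes (96.3%), and genomic span from the table's own coordinates. Tables and figures were handled with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9. Genes with near-identical copies, including histone genes, pseudogenes, RAET1L, NPY4R and the AKR1C genes, are uncertain, since the handling of reads shared between copies is not given in the sources used here.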

Results

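RNA abundance was profiled in SK-OV-3 ovarian carcinoma cells expressing shScramble or 1 of 3 shRNAs against PRMT1, untreated or after 24 h in 20 µM cisplatin, with 2 biological replicates in each of 8 groups. The series concerns PRMT1 in the response to replication stress, so the comparisons ask what cisplatin does to the transcriptome and whether loss of PRMT1 alters it. Library totals recovered from the RPKM values ran from 12289319 to 16039782 reads. Between 27642 and 29236 genes had at least 1 read in a library.

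PRMT1 itself (ENSG00000126457.16, GRCh37 chromosome 19, 50179042 to 50192286, plus strand) was lower in all 12 shPRMT1 libraries than in any shScramble library. It measured 21.4 ± 2.94 RPKM (SD, n = 2) in untreated shScramble cells and 6.61 ± 1.84 RPKM (SD, n = 6) in untreated shPRMT1 cells. Under cisplatin the means were 19.2 ± 1.93 (n = 2) and 5.9 ± 2.44 RPKM (n = 6). As a share of the shScramble mean, PRMT1 stood at 28.8% untreated and 27.6% under cisplatin with shRNA #1, at 24.2% and 21.6% with #3, and at 39.4% and 43.1% with #5. The log2 difference averaged over the shRNAs was -1.59 (SE 0.22, adjusted p = 0.00179) untreated and -1.61 (SE 0.22, adjusted p = 0.000763) under cisplatin. Cisplatin gave a log2 difference in PRMT1 of -0.15 (SE 0.26, adjusted p = 0.733) in shScramble cells and -0.17 (SE 0.15, adjusted p = 0.379) in shPRMT1 cells, neither past the threshold. Knockdown by #5 was called with all libraries (adjusted p = 0.0115 untreated, 0.0106 under cisplatin). It lost the call untreated without shScramble untreated replicate 2 (-1.11, adjusted p = 0.0846) or without #5 untreated replicate 1 (-1.24, 0.0596) or 2 (-1.25, 0.0612), and under cisplatin without shScramble cisplatin replicate 2 (-1.06, 0.0700) or #5 cisplatin replicate 1 (-0.82, 0.0889).

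**Figure D1:**
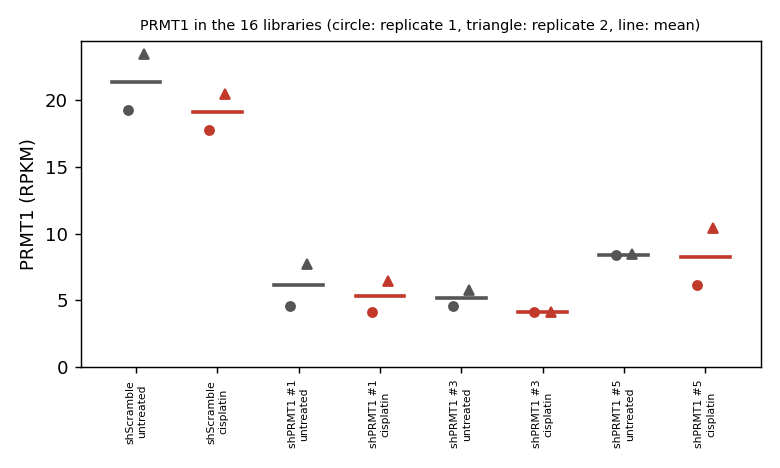
PRMT1 level in RPKM on a linear axis for each of the 16 libraries, grouped by shRNA and treatment, with circles for replicate 1, triangles for replicate 2 and lines for group means. The shScramble libraries lie between 17.8 and 23.5 RPKM and the shPRMT1 libraries between 4.12 and 10.4 RPKM.

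In shScramble cells cisplatin raised genes of the SASP and NF-kB lists. TNFAIP3 (chromosome 6, 138188350 to 138204449), a feedback inhibitor of NF-kB, rose from 1.75 ± 0.477 to 65.5 ± 1.9 RPKM (SD, n = 2 and 2), a log2 change of 4.61 (SE 0.13, adjusted p = 1.9e-08). The chemokine CCL20 rose by 4.38 (SE 0.20), the costimulatory receptor TNFRSF9 by 4.26 (SE 0.10), TNF by 4.13 (SE 0.19), IL1A by 3.81 (SE 0.25), IL6 by 3.77 (SE 0.13), IL1B by 3.51 (SE 0.19) and IL8 by 3.17 (SE 0.20). RAET1L, a ligand of a natural killer cell receptor, and ESM1, a secreted proteoglycan, rose by 4.18 (SE 0.15) and 3.85 (SE 0.18). The largest decreases were in ARL15, a small GTPase gene, which dropped from 13.5 ± 2.18 to 0.142 ± 0.0531 RPKM, and in TENM1, TMEM117, the receptor tyrosine phosphatases PTPRG and PTPRM, the mTOR inhibitor DEPTOR, FAM172A and GMDS. Their log2 changes ran from -3.66 to -3.03.

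Of 37 measured SASP genes, 23 rose and 5 fell (24 and 6 adjusted over the list alone), and of 21 NF-kB genes 17 rose (17 adjusted over the list alone), with CD83 at 2.69, BIRC3 at 3.10 and TRAF1 at 3.24. Camera called both higher (adjusted p = 1.38e-09 and 1.56e-11). Of 37 S phase and DNA replication genes, 25 rose and none fell (27 adjusted over the list alone, camera adjusted p = 1.56e-11), among them cyclin E gene CCNE1 by 1.5 (SE 0.10), E2F2 by 1.60, MCM10 by 1.21 and DTL by 1.43. Of 26 p53 target genes, 10 rose and 3 fell (10 and 3 adjusted over the list alone, camera adjusted p = 0.000938). The cell-cycle inhibitor gene CDKN1A rose by 2.43 (SE 0.14), BTG2 by 1.86, AEN by 2.14 and GADD45A by 1.33, in a line known to lack p53. Of 25 ATF4 and endoplasmic reticulum stress genes, 16 rose and 1 fell (16 and 2 adjusted over the list alone, camera adjusted p = 8.52e-07), led by ATF3 at 3.59 (SE 0.10). These 5 list calls held with an estimated correlation.

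Other lists passed at the preset correlation and with fry, but not with an estimated correlation. Of 24 AP-1 and immediate early genes 18 rose (18 adjusted over the list alone, camera adjusted p = 9.88e-11), including DUSP5 by 1.81, KLF4 by 2.47 and KLF6 by 0.95, with adjusted p = 0.107 with an estimated correlation. Of 38 DNA damage response genes 16 rose and 2 fell (16 and 2 adjusted over the list alone, camera adjusted p = 0.00631), with adjusted p = 0.469 with an estimated correlation. The Fanconi anemia genes FANCG, FANCA and FANCE rose by 0.74, 0.70 and 0.73. Of 21 cholesterol synthesis genes 6 fell, INSIG1 among them, and 9 fell adjusted over the list alone (camera adjusted p = 0.00795), with adjusted p = 0.134 with an estimated correlation. Of 21 NRF2 genes 1 rose, heme oxygenase HMOX1, and 7 fell, the aldo-keto reductases AKR1C1, AKR1C2 and AKR1C3 among them (1 and 7 adjusted over the list alone, camera adjusted p = 0.0354), with adjusted p = 0.321 with an estimated correlation. The G2 and mitosis list, with 2 of 31 higher and 8 lower (2 and 8 adjusted over the list alone), missed the threshold (camera adjusted p = 0.0536) and passed it with the replicate block (0.0292), with adjusted p = 0.731 with an estimated correlation. KIF20A fell by 0.91 and CCNB1 fell by 0.51. The arginine methyltransferase, interferon, metallothionein, ribosomal, epithelial and mesenchymal, and other-cell marker lists did not pass (camera adjusted p from 0.0728 to 0.984). For the ribosomal list the median was -0.02 and the mean 0.02. The collagen genes COL1A2 and COL3A1 of the marker list fell by 2.49 and 1.69. Under the replicate block 2 ATF4 genes and 12 cholesterol genes fell and 1 cholesterol gene rose, and 2 NRF2 genes rose and 11 fell.

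Across 18149 genes, 2815 rose and 2659 fell after cisplatin in shScramble cells, of which 657 and 761 changed at least 2-fold, and all 5474 kept their sign in both replicate numbers. The calls were made on these same libraries, so that agreement was all but fixed by the calling and is no separate support. The number higher was 1852 without shScramble untreated replicate 2, and the number lower was 1683 without shScramble cisplatin replicate 2. The call of HMOX1 ended without shScramble untreated replicate 1 or cisplatin replicate 2 (adjusted p = 0.0671 and 0.0569).

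In shPRMT1 cells cisplatin also raised cytokine genes, with IL11 at the head of the SASP list. IL11 rose from 1.18 ± 0.513 to 20.2 ± 2.91 RPKM (SD, n = 6 and 6), a log2 change of 3.30 (SE 0.09, adjusted p = 1.68e-09). RAET1L rose by 3.64 (SE 0.09), ZNF280A by 3.54, HAP1 by 3.25, RND1 by 2.92, the transcription factor SNAI1 by 2.79, MUC13 by 2.67 and the growth factor HBEGF by 2.60. DEPTOR (chromosome 8, 120885956 to 121063152) fell from 17.2 ± 7.9 to 0.219 ± 0.152 RPKM, and TMEM117, FARS2, UST, LRRC16A, KIF16B, GRID1 and SH3RF3 fell too, with log2 changes from -3.34 to -2.76. IL6 rose by 1.87, IL1B by 1.17, IL8 by 1.01 and IL1A by 1.00.

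Of 37 SASP genes, 19 rose and 5 fell in shPRMT1 cells (19 and 6 adjusted over the list alone, camera adjusted p = 0.0021). Of 37 S phase genes, 29 rose and 1 fell (29 and 1 adjusted over the list alone, camera adjusted p = 2.71e-09), with CCNE1 up by 1.55, CLSPN by 1.5 and CDC6 by 1.14. Of 26 p53 target genes, 14 rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 0.0021), CDKN1A by 1.88 and PMAIP1 by 0.77 among them. These 3 calls held with an estimated correlation. Of 21 NF-kB genes 14 rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 0.000349), with adjusted p = 0.0899 with an estimated correlation. Of 25 ATF4 genes 16 rose and 1 fell, VLDLR (18 and 1 adjusted over the list alone, camera adjusted p = 0.000995), with adjusted p = 0.104 with an estimated correlation. Of 24 AP-1 genes 20 rose (20 adjusted over the list alone, camera adjusted p = 2.21e-06), with adjusted p = 0.224 with an estimated correlation. Of 40 ribosomal protein genes 28 rose (30 adjusted over the list alone, camera adjusted p = 4.56e-05), RPS24 by 0.72 and RPL37 by 0.58, with adjusted p = 0.27 with an estimated correlation. Whether library totals contribute to the ribosomal changes, here and in the later comparisons, was not tested. The reason for this limit is given with the reads per base in the last section. Of 21 cholesterol synthesis genes 11 fell (12 adjusted over the list alone, camera adjusted p = 0.0011), HSD17B7 and INSIG1 among them, with adjusted p = 0.0899 with an estimated correlation.

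The other 8 lists did not pass in this comparison (camera adjusted p from 0.0566 to 0.846), and their members moved both ways. Of 38 DNA damage response genes 19 rose and 6 fell (19 and 6 adjusted over the list alone). ATRIP rose by 0.91 and FANCC fell by 1.33, and the list passed with the replicate block (adjusted p = 0.0345), with adjusted p = 0.59 with an estimated correlation. Of 31 G2 and mitosis genes 5 rose and 12 fell (5 and 12 adjusted over the list alone), and that list passed with the block as well (0.0241), with adjusted p = 0.59 with an estimated correlation. Of 28 interferon-stimulated genes 11 fell, IFIT1 at -1.5 among them, and 2 rose (2 and 11 adjusted over the list alone). Of 21 NRF2 genes 5 rose and 9 fell (5 and 9 adjusted over the list alone), and of 23 epithelial and mesenchymal genes 5 rose and 9 fell (5 and 9 adjusted over the list alone), with the fibronectin gene FN1 at -1.11. In the marker list CD79A and CD14 rose by 0.97 and 0.94 while COL1A2 and COL3A1 fell by 1.53 and 1.28. CD79A and CD14 passed the low-value filter only through the treated shPRMT1 libraries, so their rise was a condition of testing them. With the block 2 p53 target genes and 2 ATF4 genes fell, 8 G2 and mitosis genes rose and 5 interferon-stimulated genes rose. Across all genes 5510 rose and 4283 fell, 614 and 941 at least 2-fold, all with the same sign in both replicate numbers, which the calling on these libraries again favored.

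**Figure D2:**
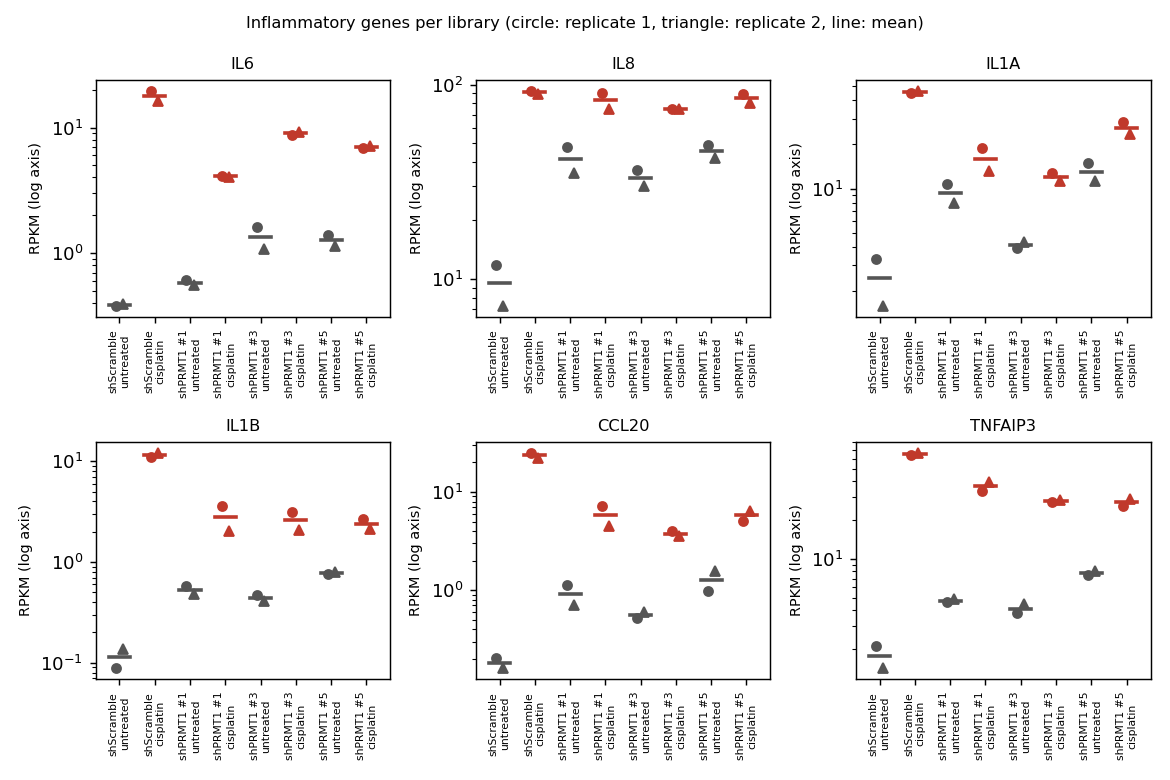
RPKM on a log axis for IL6, IL8, IL1A, IL1B, CCL20 and TNFAIP3 in each of the 16 libraries, with circles for replicate 1, triangles for replicate 2 and lines for group means. CCL20 has a mean of 0.182 RPKM in untreated and 23.7 RPKM in cisplatin-treated shScramble cells, against 0.917 and 5.13 RPKM in shPRMT1 cells.

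Without cisplatin, PRMT1 knockdown raised HMOX1 and genes of the SASP list. The heme oxygenase gene HMOX1 (chromosome 22, 35776353 to 35790207) stood at 42.7 ± 7.79 RPKM (SD, n = 6) against 7.69 ± 1.19 (n = 2) in shScramble cells, a log2 difference of 2.32 (SE 0.13, adjusted p = 1.33e-05). IL8 stood at 40.0 ± 7.56 against 9.49 ± 3.22 RPKM (log2 difference 1.98, SE 0.16). ATF3 was higher by 1.61 (SE 0.08), IL1A by 1.43, the carboxypeptidase CPA4 by 1.85, LINC00973 by 1.86, LMCD1 by 1.46, and the histone genes HIST1H4H and HIST1H2BD by 2.42 and 1.68. IL6 was higher by 0.55 (adjusted p = 0.0106), and IL1B gave 0.50 (adjusted p = 0.0793, 0.0297 with the replicate block). The IL1B difference was 1.66 (0.00221) with a pseudocount of 0.1, 2.23 (0.0224) with voom, and 0.50 (0.0379) with only the untreated libraries. Beside PRMT1, the mucin gene MUC5AC (-2.02), the aldehyde dehydrogenase ALDH3A1 (-1.53), PRRX1 (-1.48), ARL14 (-1.27), SNORA31 (-1.18), KRT14 (-1.18) and the pseudogene HNRNPA1P33 (-1.28) were lower.

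Of 37 SASP genes 11 were higher and 3 lower after knockdown (16 and 5 adjusted over the list alone, camera adjusted p = 0.000885), with CXCL2 at 0.92 and MMP3 at 1.12. MMP3 reached the filter of 1 RPKM only in shPRMT1 libraries, so being high there was a condition of testing it. Of 37 S phase genes none was higher and 10 were lower (16 adjusted over the list alone, camera adjusted p = 4.87e-09), with MCM3 at -0.36, MCM4 at -0.35, E2F2 at -0.64 and TYMS at -0.40. Both calls held with an estimated correlation. The S phase decrease was uneven over the shRNAs. With #1, #3 and #5 MCM3 stood at 57, 35 and 46.4 RPKM against 58.5 in shScramble cells, and MCM4 at 34.6, 25.4 and 22.7 against 34.9. TYMS stood at 26.2, 19.3 and 19.3 against 28.5, and E2F2 at 3.21, 2.58 and 2.22 against 4.68. The list was not tested for single shRNAs. Of 25 ATF4 genes 8 were higher (11 and 1 lower adjusted over the list alone, camera adjusted p = 0.000899), DDIT3 by 0.76 and SESN2 by 1.11, with adjusted p = 0.189 with an estimated correlation. Of 21 NF-kB genes TNFAIP3 and CD83 were higher, by 1.21 and 1.03 (5 adjusted over the list alone, camera adjusted p = 0.0029), with adjusted p = 0.189 with an estimated correlation. Of 24 AP-1 genes 6 were higher and 1 lower (7 and 2 adjusted over the list alone, camera adjusted p = 0.00249), with adjusted p = 0.466 with an estimated correlation. Of 5 metallothioneins MT1F and MT1X were higher, by 1.34 and 0.49 (4 adjusted over the list alone, camera adjusted p = 0.00242), with adjusted p = 0.203 with an estimated correlation. MT1F stood at 0.425 RPKM in untreated shScramble cells and reached the filter of 1 RPKM only in shPRMT1 libraries. Being high there was a condition of testing it, and the count and test of this short list rest partly on it. The G2 and mitosis list had 3 of 31 lower, FOXM1, KIF20A and MKI67 (3 adjusted over the list alone, camera adjusted p = 0.000859), with adjusted p = 0.466 with an estimated correlation. The ribosomal list had 3 of 40 lower, RPS23, RPL37 and RPL23 (2 adjusted over the list alone, camera adjusted p = 0.00605), with adjusted p = 0.481 with an estimated correlation. Under the replicate block 6 SASP genes were lower, 7 NF-kB genes higher and 1 lower, 22 S phase genes lower, 13 ATF4 genes higher and 3 lower, 10 AP-1 genes higher and 2 lower, 4 metallothioneins higher, 8 G2 and mitosis genes lower and 7 ribosomal genes lower.

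The 8 other lists did not pass untreated (camera adjusted p from 0.073 to 0.843). Of 26 p53 target genes 6 were higher and 2 lower (6 and 2 adjusted over the list alone), with the nucleotide excision repair gene DDB2 at -0.78. Of 38 DNA damage response genes 3 were lower, FANCD2 and RPA1 among them (3 adjusted over the list alone), and with the replicate block 3 were higher and 6 lower. None of 7 other arginine methyltransferase genes was called without the replicate block, nor adjusted over the list alone, and 1 was higher with it, PRMT3, picked out after its values were seen (0.21, adjusted p = 0.26, 0.0435 with the block). For this list the median was -0.07 against a mean of 0 and a test direction upward. Without the block no interferon or cholesterol gene was called, and with it 1 interferon gene was higher, and 3 cholesterol genes were higher and 1 lower. Across all genes 800 were higher and 696 lower, 71 and 42 at least 2-fold, with 4052 genes at an unadjusted p under 0.05. With the replicate block the counts were 1939 and 1749. The counts fell to 299 and 159 without shScramble untreated replicate 1, to 184 and 187 without replicate 2, and to 388 and 319 with only the untreated libraries. The calls of IL6, KRT14, HNRNPA1P33, SESN2, RPA1, MKI67, MT1X, RPL23 and RPL37 ended without either shScramble untreated replicate (adjusted p from 0.0511 to 0.257), those of E2F2, FOXM1, TYMS and FANCD2 without replicate 1 (0.0523 to 0.122), and those of ALDH3A1 and KIF20A without replicate 2 (0.0825 and 0.0635). HNRNPA1P33, MKI67, MT1X and RPL23 also lost the call without 1 or more of the other libraries (0.0508 to 0.101). With shRNA #5 left out of the mean RPA1 gave -0.12 (adjusted p = 0.268), and without #3 FANCD2 gave -0.14 (0.335). The calls of IL6, RPA1, FANCD2, MKI67, MT1X and RPL23 also ended with only the untreated libraries (0.0635 to 0.116), that of HNRNPA1P33 without a filter on low values (0.0538), and that of RPL23 without the filter (0.0621) or with quantile normalization (0.0921). Those of MKI67, MT1X and RPL23 ended without some single shRNA in the mean (0.0501 to 0.114).

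Under cisplatin, shPRMT1 cells held less mRNA of the SASP and NF-kB lists than shScramble cells. The pentraxin gene PTX3 stood at 2.38 ± 0.645 RPKM (SD, n = 6) against 16.5 ± 0.545 (n = 2), a log2 difference of -2.40 (SE 0.14, adjusted p = 3.08e-05). CCL20 gave a log2 difference of -2.04, IL1B -1.83, BIRC3 -1.70, TNFRSF9 -1.62, IL1A -1.38 and IL6 -1.35. The epithelial transcription factor EHF, the receptor gene NPY4R and the endothelin EDN2 gave -1.70, -1.75 and -1.62. IL8 measured 80.9 ± 7.17 against 91.3 ± 2.58 RPKM (log2 difference -0.18, adjusted p = 0.52), and IL11, picked out after its values were seen, was higher by 0.68 (adjusted p = 0.00397). The histone genes HIST1H2BG, HIST1H2BH, HIST1H4H, HIST1H2AC and HIST1H3E were higher by 2.31, 2.19, 1.98, 1.51 and 1.45, and RPS15AP36, SNORA2B and CCDC168 by 1.87, 1.69 and 1.56.

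Of 37 SASP genes 17 were lower and 7 higher (18 and 9 adjusted over the list alone, camera adjusted p = 5.84e-05), and of 21 NF-kB genes 11 were lower and 1 higher (13 and 1 adjusted over the list alone, camera adjusted p = 2.23e-07). INHBA gave -1.43, CXCL1 -0.74, CXCL2 -0.95, TNFAIP3 -1.08 and TRAF1 -1.34. Both list calls held with an estimated correlation. Among the lower NF-kB genes, BCL2A1 (-1.11) reached the filter of 1 RPKM only in cisplatin-treated shScramble libraries. Being high there was a condition of testing it, here and for the response to cisplatin. Of 37 S phase genes 11 were lower (12 adjusted over the list alone, camera adjusted p = 2.54e-05), with E2F2 at -1.21 and POLA1, the catalytic subunit of DNA polymerase alpha, at -1.0, and adjusted p = 0.0829 with an estimated correlation. Of 38 DNA damage response genes 6 were lower and 2 higher (6 and 2 adjusted over the list alone, camera adjusted p = 0.0243), FANCC at -1.08 and FANCD2 at -0.61, with adjusted p = 0.663 with an estimated correlation. The G2 and mitosis list had KIF11 lower at -0.36 (none adjusted over the list alone, camera adjusted p = 0.0243), with adjusted p = 0.688 with an estimated correlation. Of 21 NRF2 genes 7 were higher (8 adjusted over the list alone, camera adjusted p = 0.00214), HMOX1 by 1.17 and FTL by 0.29, with adjusted p = 0.217 with an estimated correlation. Of 40 ribosomal genes 10 were higher and 1 lower (13 and 1 adjusted over the list alone, camera adjusted p = 0.00131), with adjusted p = 0.511 with an estimated correlation. Of 5 markers of other cell types 4 were higher (4 adjusted over the list alone, camera adjusted p = 0.000942), with adjusted p = 0.0691 with an estimated correlation. Of these, CD14 stood at 1.53 ± 0.6 against 0.195 ± 0.0714 RPKM and COL1A2 at 4.33 ± 1.31 against 2.09 ± 0.0186 RPKM. CD14 and CD79A reached the filter of 1 RPKM only in cisplatin-treated shPRMT1 libraries. Being high there was thus a condition of testing them, so the count and the list test cannot be read as a result about this list. Under the replicate block 20 S phase genes were lower, 5 DNA damage response genes higher and 12 lower, 9 G2 and mitosis genes lower, and 19 ribosomal genes higher and 3 lower.

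The remaining 8 lists did not pass under cisplatin (camera adjusted p from 0.191 to 0.923). Among them DDB2 was lower at -0.98, the early growth response genes EGR2 and EGR3 at -1.27 and -0.75, and the arginine methyltransferase PRMT5 was higher at 0.23. SNAI1 was higher by 1.18 (adjusted p = 0.0132). Across all genes 1894 were higher and 1699 lower, 175 and 132 at least 2-fold, so that 52.7% of calls were higher, against 37.3% with voom on the recovered reads (1331 higher, 2234 lower). With the replicate block the counts were 3287 and 3001. They were 583 and 520 without shScramble cisplatin replicate 1, 769 and 974 without replicate 2, and 944 and 915 with only the cisplatin libraries. The calls of HIST1H3E, COL1A2, SNAI1 and KIF11 ended without either shScramble cisplatin replicate (adjusted p from 0.0578 to 0.322), that of PRMT5 without replicate 1 (0.141), and those of EDN2 and FTL without replicate 2 (0.107 and 0.0625). KIF11 lost it without 8 other libraries too (0.053 to 0.0796), and PRMT5 with voom (0.0756). With quantile normalization FTL gave 0.08 (0.0741). COL1A2, SNAI1 and KIF11 were not called with only the cisplatin libraries (0.0511 to 0.0931), and KIF11 not without the low-value filter (0.0895) or without #3 or #5 in the mean (0.0738 and 0.0641).

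The response of SASP and NF-kB genes to cisplatin was lower in shPRMT1 than in shScramble cells. TNFRSF9 (chromosome 1, 7979906 to 8000926) rose with cisplatin from 0.182 to 21.6 RPKM in shScramble cells and from 2.05 to 6.36 RPKM in shPRMT1 cells, a difference in log2 response of -2.97 (SE 0.12, adjusted p = 1.73e-06). The differences for IL1A, CCL20, PTX3, IL1B, IL32, TNFAIP3 and TNF ran from -2.81 (SE 0.29) to -2.29 (SE 0.22), and IL8 and IL6 gave -2.16 (SE 0.23) and -1.89 (SE 0.15). For IL8 this came mostly from a higher untreated level, 40 RPKM in shPRMT1 against 9.49 in shScramble cells. Its levels under cisplatin were 80.9 and 91.3 RPKM. Responses were more positive in shPRMT1 cells for HIST1H2BH (2.45), MUC5AC (1.77), RPS15AP36 (1.72), TENM1 (1.65), CCDC168 (1.49), HIST1H2AM (1.48), PCDH10 (1.39) and POLG2 (1.30). POLG2, the accessory subunit of the mitochondrial DNA polymerase, went from 10.2 to 7.28 RPKM in shScramble cells and from 9.42 to 18.3 RPKM in shPRMT1 cells.

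Of 37 SASP genes 16 had a lower response and 1 a higher (18 and 5 adjusted over the list alone, camera adjusted p = 1.82e-09), with INHBA at -2.09 and CXCL2 at -1.87. Of 21 NF-kB genes 10 had a lower response (14 adjusted over the list alone, camera adjusted p = 1.06e-11), BIRC3 at -2.08 and CD83 at -1.65. Both held with an estimated correlation (adjusted p = 0.00261 and 0.0095 with an estimated correlation). Of 25 ATF4 genes 7 had a lower response (8 adjusted over the list alone, camera adjusted p = 6.27e-05), ATF3 at -1.44 and TRIB3 at -1.40, with adjusted p = 0.103 with an estimated correlation. Both genes started higher in untreated shPRMT1 than shScramble cells, ATF3 at 10.7 against 2.84 RPKM and TRIB3 at 14 against 5.91. Under cisplatin they stood at 50.8 against 45 and at 19.4 against 22.9 RPKM. The ATF4 list had a median of -0.04 for knockdown under cisplatin (camera adjusted p = 0.544). Of 24 AP-1 genes 6 had a lower response (7 and 1 higher adjusted over the list alone, camera adjusted p = 3.98e-06), EGR2 at -1.20 and KLF4 at -1.09, with adjusted p = 0.299 with an estimated correlation. KLF4 too was higher untreated in shPRMT1 cells (9.28 against 3.57 RPKM) and near equal under cisplatin (25.8 against 24.3). EGR2 was instead lower under cisplatin (0.729 against 3.12 RPKM). The ribosomal list moved upward with RPL30 called (1 adjusted over the list alone, camera adjusted p = 3.42e-08), with adjusted p = 0.198 with an estimated correlation. Of 5 markers of other cell types COL1A2 and CD14 had a higher response (3 adjusted over the list alone, camera adjusted p = 0.0128), with adjusted p = 0.162 with an estimated correlation. The limit set by the filter for CD14 and CD79A holds here too. Under the replicate block 6 SASP genes, 2 AP-1 genes and 8 ribosomal genes had a higher response.

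The other 10 lists did not pass (camera adjusted p from 0.111 to 0.707), although HMOX1 (-1.15), FANCC (-0.83), POLA1 (-0.92) and MT1F (-0.95) were called. For MT1F the limit set by the filter applies here as well. For the epithelial and mesenchymal list the median was 0.06 and the mean 0.02 with a test direction downward, and for the S phase list the median was 0.04 and the mean -0.02. Across all genes 378 had a higher and 564 a lower response, 97 and 138 by at least 2-fold. The higher share was 40.1%, against 24.6% with voom (232 higher, 712 lower). Long genes were frequent among the 564: 202 spanned 100 to 300 kb and 90 over 300 kb, 9.7% and 20.4% of the genes tested in those ranges. Under 10 kb 72 were lower, 1% of the genes tested. A higher response was called for 0.5%, 3.9% and 3% of the genes in these ranges, in the same order. Of the 564, 298 had risen with cisplatin in shScramble cells, where independent lists would share 87.5, and 168 were higher in untreated shPRMT1 cells, where independent lists would share 24.9. These comparisons share libraries, so part of the excess may come from the shared libraries. With the replicate block the counts were 1125 and 1412. They fell to 69 and 130 without shScramble cisplatin replicate 1, 135 and 338 without its replicate 2, 138 and 320 without shScramble untreated replicate 1, and 100 and 150 without its replicate 2. Without a library of shRNA #3 they were 213 and 347 (untreated replicate 1), 226 and 355 (untreated replicate 2), 222 higher (cisplatin replicate 1), and 234 and 351 (cisplatin replicate 2), and 240 were higher with quantile normalization. TNFRSF9, IL1A, CCL20, PTX3, IL1B, IL32, TNFAIP3, TNF, IL6 and IL8 were called under every alternative run. The calls of HIST1H2AM, CCDC168, RPS15AP36, PCDH10, MUC5AC and FANCC ended without 1 or more of the 4 shScramble libraries, cisplatin replicate 1 in each case (adjusted p from 0.0511 to 0.177), and those of CD14, COL1A2, MT1F, TRIB3 and RPL30 without any 1 of the 4 (0.0549 to 0.224). HIST1H2AM, CD14, COL1A2, MT1F and TRIB3 also lost the call without 1 or more shPRMT1 libraries (0.0516 to 0.0905). With voom the calls of HIST1H2AM (adjusted p = 0.076), RPS15AP36 (0.122), CCDC168 (0.143), MT1F (0.191) and CD14 (0.47) ended, and the MUC5AC difference was 0.03 (0.997). With a pseudocount of 0.1 those of MUC5AC, HIST1H2AM, RPS15AP36, CD14 and MT1F ended (0.0503 to 0.176), without the low-value filter those of HIST1H2AM, CD14, COL1A2, MT1F and TRIB3 (0.0579 to 0.0887), and without some single shRNA in the mean those of HIST1H2AM, CD14, COL1A2, MT1F, TRIB3 and RPL30 (0.0534 to 0.123).

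The 3 shRNAs were also compared singly. Cisplatin raised 2875 genes and lowered 2528 with #1, 3461 and 3090 with #3, and 3498 and 3047 with #5, and 1984 and 2054 genes were called in the same direction with all 3. Untreated, 804 genes were higher and 846 lower with #1 than with shScramble, 754 and 714 with #3, and 1255 and 1182 with #5. Under cisplatin these were 905 and 1075, 1277 and 1242, and 2194 and 1893. The difference in response was called upward and downward for 89 and 177 genes with #1, 226 and 356 with #3, and 239 and 396 with #5. Called in the same direction with all 3 were 208 and 82 genes untreated, 462 and 464 under cisplatin, and 36 and 112 for the difference in response. Simulated groups without any change, set against shared simulated shScramble libraries, gave at most 0 in either direction in 100 draws. With no change in any group hardly any gene is called, so that overlap was all but fixed in advance. It does not test the agreement of the shRNAs. A shScramble population that differs from all 3 shRNAs was not simulated. Independent lists would share 2.3 and 2.2, 7.7 and 7.7, and 0 and 0.1. With the replicate block cisplatin raised 4349 genes with #1, and 3113 and 2762 genes were called upward and downward with all 3. Against shScramble the single counts were then 2130 and 1963, 1882 and 1579, and 2568 and 2191 untreated, 2222 and 2252, 2452 and 2415, and 3805 and 3094 under cisplatin, and 414 and 693, 826 and 1148, and 973 and 1160 for the response, and those shared by all 3 were 496 and 270, 1092 and 1042, and 177 and 393. The log2 differences of the shRNAs correlated across genes, which are not independent replicates, at 0.41 to 0.51 untreated, 0.68 to 0.72 under cisplatin and 0.67 to 0.70 for the response, where shared shScramble libraries alone gave 0.5. The mean covariances were 0.059, 0.114 and 0.122 against simulated values of 0.031, 0.031 and 0.062. With 2 shScramble libraries per treatment the controls could not be divided, so part of the excess may come from the shared controls.

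Genes with a long genomic span fell often after cisplatin. Of 441 tested genes spanning over 300 kb, 72.8% were lower in shScramble cells and 88.7% in shPRMT1 cells, with median log2 changes of -1.0 and -1.20. Of 2079 genes spanning 100 to 300 kb the shares were 35.6% and 62%, and of 7144 genes under 10 kb they were 8.3% and 11.6%. The shPRMT1 shares rest on more libraries than the shScramble shares, so more genes can pass the threshold there. The shares are therefore not comparable between the cells as sizes of effect. Over all spans, single shRNAs lowered 2528, 3090 and 3047 genes, each with as many libraries as shScramble. The mean of the shRNAs lowered 4283, and 2659 fell in shScramble cells. TENM1 on chromosome X (123509752 to 124097666) and ARL15 on chromosome 5 (53179774 to 53606412) belong to the longest group. Across genes, which are not independent replicates, span and log2 change had a Spearman correlation of -0.10 in shScramble cells and -0.31 in shPRMT1 cells. Span and the difference in response had a correlation of -0.34.

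**Figure D3:**
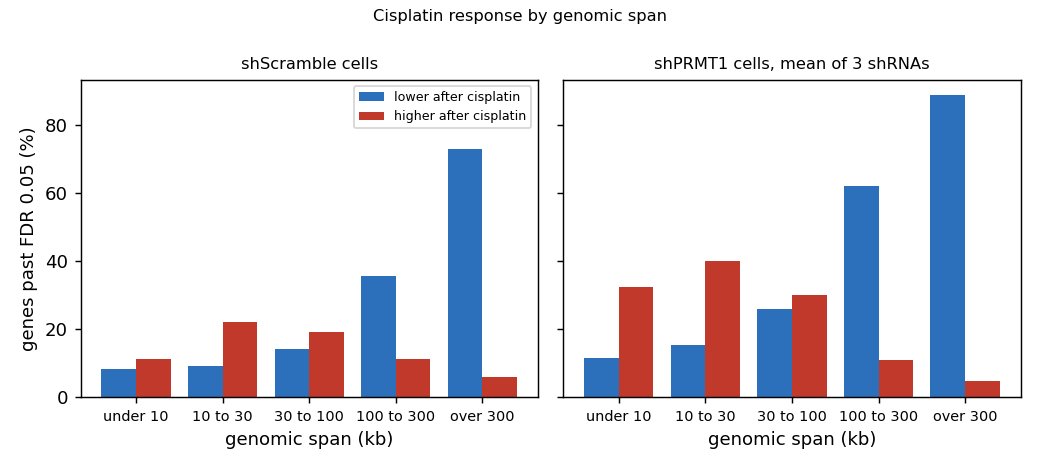
Percentage of tested genes higher or lower after cisplatin at an adjusted p under 0.05, by genomic span in kb, in shScramble cells and in shPRMT1 cells averaged over the 3 shRNAs. The share of lower genes is 8.3% under 10 kb and 72.8% over 300 kb in shScramble cells, and 11.6% and 88.7% in shPRMT1 cells. The shPRMT1 shares rest on more libraries, so more genes can pass the threshold. The shares are not comparable between the cells as sizes of effect.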

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

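Chosen only after the result was seen were the histone set and the tests of each shRNA held out, of small non-coding RNA, and of the direction by line and replicate. The same holds for the tests of span within quintiles in shPRMT1 cells, of quartile genes matched by level in either cells, and for all tests on genes over 300 kb. SEs in this section come from 500 bootstrap draws of genes, unlike the SEs of single genes above. Genes are not independent replicates, so these SEs carry no variation between libraries or cultures.

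The cisplatin response differed between shPRMT1 and shScramble cells by a direct test of that difference, for 378 genes upward and 564 downward. Long genes were frequent among the latter, with 20.4% of genes over 300 kb called lower against 1% of genes under 10 kb. The named genes with a weaker or more negative response were TNFRSF9 (-2.97), IL1A (-2.81), CCL20 (-2.71), PTX3 (-2.63), IL1B (-2.33), IL32 (-2.31), TNFAIP3 (-2.29) and TNF (-2.29). Those with a more positive response were HIST1H2BH (2.45), MUC5AC (1.77), RPS15AP36 (1.72), TENM1 (1.65), CCDC168 (1.49), HIST1H2AM (1.48), PCDH10 (1.39) and POLG2 (1.30). With voom the MUC5AC difference was 0.03 (adjusted p = 0.997), and RPS15AP36, CCDC168 and HIST1H2AM were not called (0.122, 0.143 and 0.076). List medians that differed were -0.61 for SASP, -0.55 for NF-kB, -0.14 for ATF4, -0.31 for AP-1, 0.20 for ribosomal proteins and 0.79 for markers of other cell types. The last 4 of these did not pass with an estimated correlation (adjusted p = 0.103, 0.299, 0.198 and 0.162). In the marker list CD14 and CD79A passed the filter only through cisplatin-treated shPRMT1 libraries, so its median cannot be read as a result about the list.

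Among SASP and NF-kB genes, 26 had a lower response in shPRMT1 cells. Their median was 1.98 with cisplatin in shScramble cells, 0.76 in shPRMT1 cells, and 0.46 for knockdown without cisplatin. A ceiling on reads per base would compress high values. Inverting a ceiling of 2 reads per base moved the median difference from -1.47 only to -1.45 (SE 0.27), and all 26 stayed called. The inversion assumes reads spread evenly over a gene model, and it alters genes far below 2 reads per base little. IL6, for example, reached at most 0.29 and ACTB at most 0.82. The inversion therefore cannot decide on a ceiling that sets in lower, which stays open. An effect of 1 shRNA on other genes was argued against, since members called lower in the mean of 2 shRNAs had a median of -1.5 (SE 0.22) or below in the shRNA held out. All 3 shRNAs share the shScramble libraries, and simulating a held-out shRNA without a change against those libraries gave medians of -0.15 at the lowest in 100 draws for each. Over the whole lists, called or not, the medians for #1, #3 and #5 were -0.67 (SE 0.20), -0.32 (SE 0.27) and -0.64 (SE 0.29) for SASP and -0.41 (SE 0.24), -0.51 (SE 0.25) and -0.72 (SE 0.27) for NF-kB, so that the single shRNAs are less certain there. A property of the shScramble cells stays open, because the design holds 1 shScramble population and knockdown cannot be told apart from it, and PRMT1 loss itself, though named by the design, rests on that same control.

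Long genes fell after cisplatin in 8 of 8 pairs of line and replicate, with a least negative Spearman correlation across genes of -0.08. The test planned on quartiles of span did not separate span from other gene properties in shScramble cells. Within quintiles, the weakest difference between the longest and shortest quartile was -0.02 (SE 0.01) by GC content, 0.04 (SE 0.02) by exonic length and -0.01 (SE 0.01) by expression. The strongest were -0.20, -0.45 and -0.34. The difference thus nearly vanished in the weakest quintile of each property and remained in others. Setting each gene of the longest quartile beside the gene of nearest level in the shortest left little in shScramble cells. The median difference was -0.03 (SE 0.01) by untreated shScramble level and -0.12 (SE 0.01) by mean level. How much of the trend over quartiles these properties account for there stays open. In shPRMT1 cells the weakest difference by GC content was -0.33 (SE 0.03), which argues against GC content as the whole cause in those cells. By expression it was -0.17 (SE 0.01), and -0.33 (SE 0.01) when each gene of the longest quartile was set beside the gene of nearest level in the shortest, which argues against expression level as the whole cause in those cells. By exonic length it was -0.08 (SE 0.02), within its SE of the bound set for the cause, so exonic length stays open. For the genes over 300 kb in shScramble cells the weakest differences over quintiles with at least 20 such genes were -0.91 (SE 0.09) by GC content and -0.95 (SE 0.07) by exonic length (-0.62 in a quintile of exonic length with 18), which argues against either as the whole cause there. By expression the differences were -0.97, -1.48, -0.93 and -0.46 (SE 0.10), with -0.35 in the quintile that held 11 such genes, and -1.08 (SE 0.06) when each of these genes was set beside the gene under 30 kb of nearest level (-1.30, SE 0.07, in shPRMT1 cells), which argues against expression level as the whole cause too. Treatment with a drug that crosslinks DNA is the biological candidate the design names, as a hypothesis.

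Histone genes were higher in shPRMT1 than in shScramble cells under cisplatin, 34 of 53 called and none lower (median 0.81, or 1.26 with voom, camera adjusted p = 3.6e-19, adjusted p = 0.0187 with an estimated correlation, adjusted over the 2 sets of histone and small non-coding RNA genes). Histone genes at the head of these comparisons had prompted the set. Without the 7 named ones, 27 of 46 were higher and none lower (median 0.76, unadjusted p = 5.37e-15, unadjusted p = 0.013 with an estimated correlation). In the other 4 comparisons the histone set did not pass with an estimated correlation. The adjusted p was 0.233 for knockdown untreated with 12 higher, and 0.0582 for the difference in response with 9 higher. For cisplatin it was 0.499 in shScramble cells with 12 higher and 1 lower, and 0.0641 in shPRMT1 cells with 36 higher and 1 lower (median 0.68). More cells in S phase would predict a higher S phase list, whose median was -0.15 (SE 0.04). That argues against it only as far as these transcripts follow the share of cells in S phase, which was not measured. The list median was already -0.22 for knockdown untreated, and 0.04 for the difference in response. More non-polyadenylated RNA in those libraries stays open, since 528 small non-coding RNA genes had a median of 0.20 (SE 0.03), within its SE of the lower bound set for the test. Reads shared between near-identical histone copies were not tested, nor was PRMT1 loss apart from the shared control.

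For cisplatin against untreated in shPRMT1 cells, 9471 genes were called in a model with the shRNA as a term, and 1 of 100 splits of the 12 libraries, the real one, gave as many. The highest of the others, which depends on the splits drawn, gave 3444, in a split that matched the real one in 10 of 12 libraries, and the split by replicate number gave 1364. Of the 32 splits that part every pair of treatment within shRNA and replicate, the highest other gave 1. A chance split is thus an unlikely source of the count. The test cannot reach a share below 1 of 100, or 1 of 32 among the splits that part every pair.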

How the results depend on the processing

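Chosen only after the data had been seen were voom on recovered reads, inversion of the ceiling, and leaving each shRNA out of the mean.

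Of the results for named genes under the alternatives, 7460 kept their direction and their side of the threshold, 497 lost the call, 6 gained it and 8 reversed. For list tests the numbers were 197, 29, 12 and 2, for PRMT1 levels 103 kept and 5 lost, and for counts of genes 220 stayed within 1.5 times and 64 did not. The 8 reversals all concerned the PRMT1 difference in response, near 0 at -0.02 and from -0.15 to 0.11 over single libraries left out: 0.16 with quantile normalization, 0.03 with the mean lacking shRNA #3, and when single libraries were left out 0.11 (shScramble untreated replicate 1), 0.08 (shScramble cisplatin replicate 2), 0.09 (#1 untreated replicate 2), 0.07 (#1 cisplatin replicate 1), 0.03 (#3 untreated replicate 2) and 0.09 (#5 cisplatin replicate 1). The list of other arginine methyltransferases turned direction after cisplatin in shPRMT1 cells with fry (adjusted p = 0.341) and for knockdown untreated with the replicate block (0.847), without a call in either form. The cause was not tested.

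With the replicate block the counts were 1939 and 1749 for knockdown untreated, 3287 and 3001 for knockdown under cisplatin, and 1125 and 1412 for the difference in response. Among the lists and the genes named by rule in each comparison the block took away no call and added IL1B untreated (0.0297), the G2 and mitosis list after cisplatin in shScramble and shPRMT1 cells (0.0292 and 0.0241) and the DNA damage response list after cisplatin in shPRMT1 cells (0.0345), 3 list calls at the preset correlation (0.731, 0.59 and 0.59 with an estimated correlation). With fry the G2 and mitosis list lost its call for knockdown untreated (0.0859) and under cisplatin (0.265), the ribosomal list untreated (0.0782) and the DNA damage response list under cisplatin (0.102). Fry gained the p53 list in both (0.00191 and 0.0437), the marker list after cisplatin in shScramble cells (0.000401), and 6 lists after cisplatin in shPRMT1 cells (0.00201 to 0.0315). Of genes picked out after their values were seen the replicate block added the SNAI1 difference in response (0.012) and PRMT3 untreated (0.0435). For single shRNAs with the block, cisplatin raised 4349 genes with #1. Knockdown untreated gave 2130 and 1963 (#1), 1882 and 1579 (#3), and 2568 and 2191 (#5). Knockdown under cisplatin gave 2222 and 2252, 2452 and 2415, and 3805 and 3094. The difference in response gave 414 and 693, 826 and 1148, and 973 and 1160. A model of only the libraries compared gave 388 and 319 untreated and 944 and 915 under cisplatin, with fewer libraries to estimate the spread. For the difference in response 240 genes were higher with quantile normalization and 232 with voom. Calls required of each shRNA left 1984 and 2054 genes for cisplatin in shPRMT1 cells, 208 and 82 untreated, 462 and 464 under cisplatin and 36 and 112 for the response, by construction fewer. Without a low-value filter, with a pseudocount of 0.1, with the ceiling inverted or without any 1 shRNA, every averaged count stayed within 1.5 times.

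Leaving out 1 library leaves a lone sample that is assumed to vary like the other groups. The counts then ran from 1852 to 3156 higher and 1683 to 2918 lower for cisplatin in shScramble cells, with the lowest without shScramble untreated replicate 2 and shScramble cisplatin replicate 2. They ran from 4957 to 5685 and 3911 to 4472 for cisplatin in shPRMT1 cells. For knockdown untreated they ran from 184 to 982 and 159 to 818, lowest without shScramble untreated replicates 2 and 1, and under cisplatin from 583 to 2248 and 520 to 1904, lowest without shScramble cisplatin replicate 1. For the response they ran from 69 to 464 and 130 to 622, lowest without shScramble cisplatin replicate 1. PRMT1 ran from -2.0 to -1.35 untreated and -1.97 to -1.43 under cisplatin with #1, from -2.0 to -1.71 and -2.07 to -1.87 with #3, and from -1.38 to -1.11 and -1.49 to -0.82 with #5. The DESeq2 test and the edgeR fit with DESeq2 size factors, listed as alternatives for read counts, were not run, because the table holds RPKM. Median-of-ratios scaling entered only with voom on recovered reads. At 12289319 to 16039782 reads per library, values under about 0.1 RPKM rest on few reads.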

Other observations

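The test of a ceiling on reads was chosen only after the result was seen.

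SNAI1 and IL11 rose after cisplatin in both shScramble and shPRMT1 cells. SNAI1 reached 33.5 ± 11.3 RPKM (SD, n = 6) in cisplatin-treated shPRMT1 cells against 13.5 ± 2.08 (n = 2) in shScramble cells, with a difference in response of 1.04 (SE 0.39, adjusted p = 0.167, 0.012 with the replicate block). IL11 reached 20.2 against 12.2 RPKM, and its response differed by 0.23 (SE 0.18, adjusted p = 0.552). DDB2 was lower with knockdown in both treatments (-0.78 and -0.98), with a difference in response of -0.20 (adjusted p = 0.366). These 3 genes were singled out after their values were seen.

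No gene exceeded 1.84 reads per base of its gene model in any library, and the highest value in the table was 148 RPKM. The 13 protein-coding mitochondrial genes, which are usually among the most abundant transcripts of a cell, summed to between 15024 and 15859 reads in every library, and all genes of the mitochondrial genome together held 0.12% to 0.16% of the reads. A candidate explanation is that reads at the same position and strand were counted once. If so, reads of these genes should stay flat as the library total grows, and their log-log slope on the total was -0.01 (SE 0.06) over the 16 libraries. This remains a hypothesis, since duplicate handling is not given in the sources used here. It may compress the highest values, and 2160 genes passed 0.5 reads per base in at least 1 library.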
